A study of Mus musculus with 18 samples.

How the data were processed

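Poly(A) RNA was measured by strand-specific sequencing in spleens of adult mice, 18 libraries of 3 genotypes with 6 animals each, 3 male and 3 female. The genotypes are WT (C57BL/6J), Dp16 (an extra copy of the chromosome 16 interval from Lipi to Zbtb21) and Dp16_2xIFNRs (Dp16 in which the interferon receptor genes are back at the normal copy number). According to the labels, RNA was taken up in TRIzol, libraries were made with the Tecan Universal Plus mRNA kit and paired-end reads came from an Illumina NovaSeq. The age label runs from 17.1 to 18 under a tag of days post conception; its unit is not interpreted here.

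The deposited counts are raw whole-number read counts per gene made by the authors. The submitters' processing notes name bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5, HTSeq 0.6.1 and GRCm38, without their order or roles. The strand setting of the counting is not stated. The name of the deposited table gives the gene models as GENCODE vM24. The deposited RPKM values are the authors' counts scaled by gene length and library total. They were checked against the counts: over 11538 genes with at least 100 counts in each library, each value equalled the count divided by the library total and by 1 gene length, with a largest relative deviation of 7.8e-16. Gene positions were taken from GENCODE vM21 on GRCm38, matched by gene identifier for 55144 of 55385 genes (99.6%).

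Library totals ran from 33998427 counts (Dp16 replicate 2) to 53021480 (Dp16_2xIFNRs replicate 2). A count of 0 in a library allows up to 3 counts, which is 0.0566 to 0.0882 CPM, the unit of counts scaled to the library total. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Xist and the Y-linked genes matched the sex label in 18 of 18 libraries. Pairs of libraries within a genotype differed by a chi-square per degree of freedom of 35.5 to 204 over 45 pairs, so no library was a copy of another of its genotype.

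The choices in this paragraph and the next were made before the data were examined. Genes were filtered with filterByExpr by genotype, which kept 18634, and scaled by TMM. All 18 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (robust, R 4.3.3) with genotype and sex as terms. The contrasts were Dp16 vs WT, Dp16_2xIFNRs vs WT and Dp16_2xIFNRs vs Dp16, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. A further fit tested sex by genotype interactions. Errors of log2 fold changes are standard errors from this fit, and CPM values are group means with SD.

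Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 34 sets per contrast: 33 lists with at least 5 tested members and the triplicated region without its 4 receptor genes. Region genes were left out of the lists. The pancreatic acinar list had 3 tested members of 18 and was not tested. Camera with an estimated correlation and fry were run beside it. List scores are mean log2 CPM values per library (prior count 2), compared by a two-sided exact permutation test over the 924 splits of 12 libraries. The smallest p this test can give is 0.0021645, printed as 0.00216, and 35 score tests per contrast were adjusted together. Named genes are the 4 receptors, the 8 called genes outside the region with the smallest p in each direction (predicted genes, clones and immune receptor variable segments left out), the 5 largest called and the 3 smallest changes among protein-coding region genes for Dp16 vs WT (the smallest with a mean log2 CPM above 3), and the members with the smallest p of the lists, 4 of each interferon list and 2 of each other list called by camera. A gene that the rule picked is not reported here, and no other was put in its place. A gene named outside this rule is marked as chosen after its values were seen.

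Alternatives were other scalings (RLE, upper quartile, TMM without region genes), DESeq2 1.42.0, limma voom with quality weights, limma-trend on log2 RPKM with 0.1 added, no filter or a filter at 1 CPM in 6 libraries, an adjusted p below 0.1, a prior count of 0.5 for scores, other terms or blocks, fits on 12 libraries, omission of immunoglobulin, haemoglobin and acinar genes, and omission of each library in turn. Alternatives chosen after seeing the data were a term for the share of counts on Gm42418, omission of Gm42418 and mitochondrial genes, omission of the 4 libraries with over 4% of counts on Gm42418, and terms for the erythroid and neutrophil scores.

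The sample numbers of the titles are not known to pair animals across genotypes. After removal of genotype means, libraries with the same number had a mean correlation across genes of 0.02 over 18 pairs, against -0.004 for other numbers. A replicate block gave 3008 genes higher and 2526 lower in Dp16 vs WT, 3090 and 2706 in Dp16_2xIFNRs vs WT, and 0 and 4 in Dp16_2xIFNRs vs Dp16. Some libraries of different genotypes also share a code in their description, 7 pairs in all, whose meaning is not stated. Their correlation after removal of genotype means was -0.04 to 0.22 (mean 0.05), and the consensus correlation within codes was 0.165. With the code as a random block in limma voom, 3199 genes were higher and 2798 lower in Dp16 vs WT, 3381 and 3072 in Dp16_2xIFNRs vs WT, and 0 and 4 in Dp16_2xIFNRs vs Dp16. The exact permutations and the random splits do not take the codes into account.

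The tests were run on simulated data with 50 changed genes per fold. In the simulated Dp16 vs WT comparison edgeR recovered 10% of genes changed 1.25-fold, 32% at 1.5-fold, 72% at 2-fold and 82% at 4-fold, with 9 false calls of 107. For Dp16_2xIFNRs vs Dp16 it recovered 8%, 44%, 54% and 82%, with 4 false calls of 98. DESeq2 made 22 false calls of 133 and 15 of 116, and limma voom 5 of 103 and 3 of 96. Far fewer genes were changed there than were called in the real Dp16 vs WT comparison, so the shares recovered may not hold for it.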

Results

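Spleen transcriptomes of 18 adult mice were compared, 6 each of WT, Dp16 and Dp16_2xIFNRs, with 3 males and 3 females per genotype. Dp16 mice carry 3 rather than 2 copies of a chromosome 16 interval that matches a large part of human chromosome 21, and Dp16_2xIFNRs mice carry the same extra interval with the 4 interferon receptor genes Ifnar1, Ifnar2, Ifngr2 and Il10rb returned to 2 copies. Total counts averaged 43252453 ± 4366598 (SD, n = 6) in WT, 42190040 ± 4517774 in Dp16 and 43635905 ± 4812253 in Dp16_2xIFNRs, with 33998427 to 53021480 per library. The leading component of variation held 21.1% of the variance and the next 10.4%. Adult haemoglobin genes took 0.986% ± 0.376 of counts in WT (SD, n = 6), 2.49% ± 0.542 in Dp16 and 2.61% ± 0.590 in Dp16_2xIFNRs. Gm42418, a gene model that overlaps ribosomal RNA sequence, took 0.691% to 5.51% of counts, with means of 2.21%, 2.42% and 1.77% in the 3 genotypes.

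The comparison of Dp16 with WT asks what the extra interval changes in the spleen. Genes of the interval were higher by about their copy ratio, and the 4 receptors were higher with them. The interval spans chromosome 16 from 75540514 to 97962622 on GRCm38 (22.4 Mb) and holds 113 tested genes. Its 109 genes other than the receptors had a median log2 fold change of 0.51, a fold of 1.42, against 1.5 for the copy ratio. Of these, 98 had a positive change, 65 were called higher (70 adjusted over the list alone) and 0 lower, and camera called the set (adjusted p = 3.25e-21, and adjusted p = 4.3e-08 with an estimated correlation). The 464 tested genes of chromosome 16 outside the interval had a median of -0.01, with 78 higher and 76 lower. Among 60 protein-coding interval genes with a mean log2 CPM above 3, 48 rose, and the 95% interval lay above the copy ratio for 15 and below it for 18. Among called protein-coding interval genes at any level, predicted genes left out, the largest increases were in Itgb2l (log2 fold change 2.72 ± 0.28 SE), Chaf1b, a chromatin assembly subunit (1.79 ± 0.17), the potassium channel gene Kcnj15 (1.64), Ripk4 (1.22) and Itsn1 (1.22). Among the 60 genes, the smallest values were in Brwd1 (-0.25, adjusted p = 0.177), Adamts1 (-0.21, adjusted p = 0.699) and Ets2 (-0.14, adjusted p = 0.447). The Ripk4 call was lost without Dp16 replicate 6 (0.84, adjusted p = 0.0854) and without WT replicate 4 (1.10, adjusted p = 0.0521). It was also lost under limma voom (0.98, adjusted p = 0.0655), limma-trend on RPKM (0.78, adjusted p = 0.0576), the description-code block (1.05, adjusted p = 0.0577) and a library index term (1.06, adjusted p = 0.0539). Brwd1 passed the threshold as lower without Dp16 replicate 2 (adjusted p = 0.0336). With the erythroid and neutrophil scores as terms Itgb2l turned to -0.20 and Brwd1 to 0.71, neither called.

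**Figure D1:**
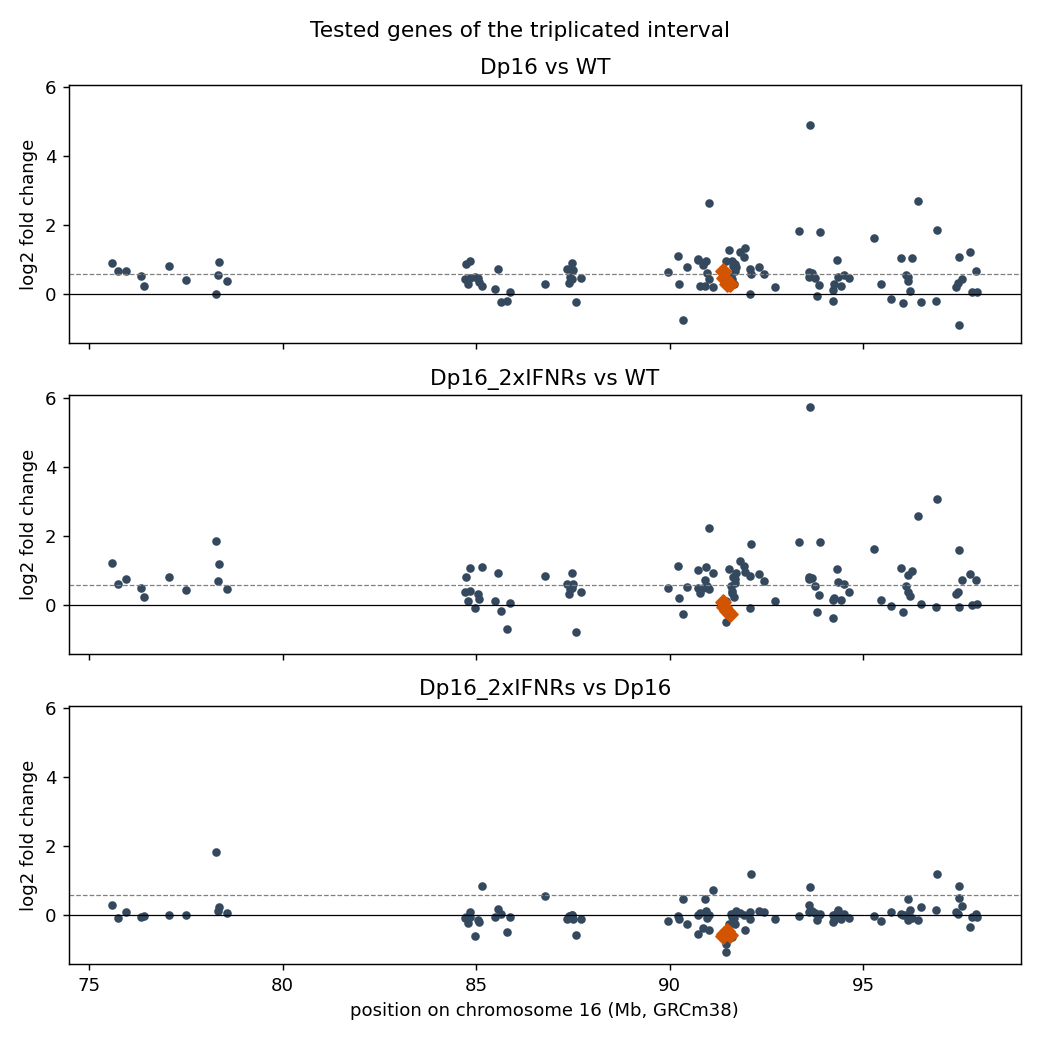
Log2 fold change (vertical axis) of tested genes of the extra interval by position on chromosome 16 in Mb (horizontal axis). Panels are Dp16 vs WT, Dp16_2xIFNRs vs WT and Dp16_2xIFNRs vs Dp16, with n = 6 per genotype. Orange diamonds are the 4 receptor genes, which stand at 0.30 to 0.68 in Dp16 and at -0.27 to 0.09 in Dp16_2xIFNRs against WT, and at -0.59 to -0.46 in Dp16_2xIFNRs against Dp16. The dashed line is the log2 copy ratio of 0.58. The point near 4.89 and 5.73 in the panels against WT is Gm5678, singled out after its values were seen, with mean CPM of 0.0034 in WT, 0.195 in Dp16 and 0.323 in Dp16_2xIFNRs.

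The receptor genes lie side by side on the plus strand of chromosome 16. Ifnar2 (91372783 to 91405589), a subunit of the type I interferon receptor, was at 88.0 ± 3.44 CPM in WT and 141 ± 7.70 in Dp16 (SD, n = 6), a fold of 1.61 (adjusted p = 2.2e-07). Il10rb (91406164 to 91425834), shared by the interleukin 10 and type III interferon receptors, was at 79.1 ± 3.96 and 109 ± 7.11 CPM, a fold of 1.38 (adjusted p = 4.8e-05). Ifnar1 (91485238 to 91507441), the other type I subunit, was at 87.3 ± 7.77 and 107 ± 12.8 CPM, a fold of 1.23 (adjusted p = 0.0062). Ifngr2 (91547072 to 91565623), of the interferon gamma receptor, was at 93.0 ± 6.55 and 115 ± 10.6 CPM, a fold of 1.23 (adjusted p = 0.0067). With limma-trend on RPKM the log2 fold change was 0.18 for both Ifnar1 (adjusted p = 0.125, from 0.30) and Ifngr2 (adjusted p = 0.12, from 0.30). Over the alternatives without the composition terms the adjusted p ran from 0.00125 to 0.125 for Ifnar1 and from 0.00174 to 0.12 for Ifngr2.

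Beyond the interval, the Dp16 spleen had higher expression of genes of granulocyte, red cell, platelet and basophil formation and of cell division, and lower expression of B cell genes. With an estimated correlation the neutrophil list alone of these kept its call, 1 of 18 lists called (adjusted p = 0.019), against an adjusted p of 0.163 for erythroid, 0.149 for platelet, basophil and cell cycle and 0.0909 for B cell genes. In all, 3091 genes were higher and 2462 lower, of which 3022 and 2462 lay outside the interval. Above 2-fold, 771 were higher and 131 lower. The called genes outside the interval with the smallest p were higher for Lin28a, a regulator of let-7 microRNA (log2 fold change 2.52 ± 0.18 SE), Wfdc21 (2.78), Ly6a2 (2.03), Ifitm6 (1.76), the neutrophil granule protein gene Pglyrp1 (1.35), the neutrophil surface gene Cd177 (2.53) and Lrg1 (1.04). The gene a (nonagouti, chromosome 2 from 154791402 to 155051012), which encodes a pigment signalling protein, was at 0.352 ± 0.219 CPM in WT and 8.11 ± 2.05 in Dp16 (SD, n = 6), a fold of 22.6. The lower genes were the IgM receptor gene Fcmr (-0.89 ± 0.09 SE), Dmpk (-0.77), B3gnt5 (-0.98), Sbk1 (-0.98), Trp53i11 (-0.68), the cell death gene Bmf (-0.93), Tlr1 (-0.61) and Pxk (-0.70). Of the called genes 55.7% were higher, against 43.4% with upper quartile scaling and 36.2% with limma-trend on RPKM, which moved the median of all genes to -0.13. With the erythroid and neutrophil scores as terms 0 genes were called by edgeR. The median standard error grew from 0.154 to 0.452, and 8 of 70 named genes turned in sign, so errors and estimates both moved. The median log2 fold change of all 113 interval genes was 0.50 before and 0.51 after.

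Granulocyte and red cell genes moved furthest. Of 18 neutrophil markers, 16 rose and 0 fell, over all genes and adjusted over the list alone, with a mean log2 fold change of 2.20 (camera adjusted p = 9.7e-39, and adjusted p = 0.019 with an estimated correlation). Among them Fcnb changed by 2.53 and S100a9, a calprotectin subunit, by 2.45, from 217 ± 112 to 1186 ± 543 CPM (SD, n = 6). The members not called were Csf3r (-0.01) and Cxcr2 (-0.19), receptors of mature neutrophils, singled out after their values were seen. All 26 erythroid markers rose (26 adjusted over the list alone; mean 1.68, camera adjusted p = 7.1e-18, adjusted p = 0.163 with an estimated correlation), among them Car1 (1.45) and Hbb-bt (1.66). All 12 haem synthesis genes rose (12 adjusted over the list alone; mean 1.38), with Cpox at 1.78 and Urod at 1.59 (camera adjusted p = 5.2e-10, adjusted p = 0.149 with an estimated correlation). All 30 cell cycle genes rose (30 adjusted over the list alone; mean 1.17), with the replicative helicase genes Mcm3 at 0.84 and Mcm5 at 0.90 (camera adjusted p = 4.9e-28, adjusted p = 0.149 with an estimated correlation).

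Of 16 megakaryocyte and platelet markers 15 rose (15 adjusted over the list alone; mean 1.09), such as Clec1b (0.70) and Gp9 (1.23, and -0.07 with the score terms), with camera adjusted p = 9.4e-13 and adjusted p = 0.149 with an estimated correlation. Of 9 mast cell and basophil markers 6 rose (6 adjusted over the list alone; mean 1.45), led by the basophil proteases Prss34 (3.32) and Mcpt8 (3.51), with camera adjusted p = 0.00015 and adjusted p = 0.149 with an estimated correlation. Of 13 antioxidant genes 11 rose (12 adjusted over the list alone; mean 0.58), such as Gsr (0.51) and Txn1 (0.58), with camera adjusted p = 2.3e-06 and adjusted p = 0.0757 with an estimated correlation. Germinal centre markers had 4 higher and 1 lower of 9 (6 and 1 adjusted over the list alone), with Neil1 at 0.46 and Gcsam at 0.66 (camera adjusted p = 0.025, adjusted p = 0.547 with an estimated correlation). Without the libraries rich in Gm42418 the calls of Neil1 (0.39, adjusted p = 0.0708) and Gcsam (0.61, adjusted p = 0.12) were lost, with fewer libraries. Unfolded protein response genes had 3 higher of 14 (3 adjusted over the list alone), among them Atf4 (0.46) and Calr (0.31), with camera adjusted p = 0.0454 and adjusted p = 0.665 with an estimated correlation. By fry its adjusted p was 0.0789, and 3 of 4 other scalings also called this list. Calr lost its call with limma-trend on RPKM (0.20, adjusted p = 0.145) and was at -0.09 with the score terms.

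B cell genes fell. Of 16 B cell markers 15 fell and 0 rose (15 and 0 adjusted over the list alone), with a mean of -0.64, Fcmr at -0.89 and the complement receptor gene Cr2 at -0.77 (camera adjusted p = 1.5e-15, adjusted p = 0.0909 with an estimated correlation). MHC class II genes had 8 lower of 11 (10 adjusted over the list alone), with H2-Ob at -0.66 and their regulator Ciita at -0.63 (camera adjusted p = 0.00014, adjusted p = 0.297 with an estimated correlation). Endothelial markers had 6 lower of 13 (7 adjusted over the list alone), with Stab2 at -0.56 and Pecam1 at -0.38 (camera adjusted p = 0.0007, adjusted p = 0.288 with an estimated correlation). Stromal markers had 6 lower of 18 (7 lower and 1 higher adjusted over the list alone), with the B cell chemokine gene Cxcl13 at -0.75 and Myh11 at -1.01 (camera adjusted p = 0.00176, adjusted p = 0.364 with an estimated correlation). NK and cytotoxic markers had 6 lower of 15 (8 adjusted over the list alone), with Eomes at -0.62 and Klrk1 at -0.37, and dendritic cell markers 7 of 14 (8 adjusted over the list alone), with Tcf4 at -0.33 and Ly6d at -0.38 (0.20 and 0.05 with the score terms). Both had a camera adjusted p of 0.00733, and an adjusted p of 0.297 and 0.149 with an estimated correlation.

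Circadian clock genes had 7 lower of 15 (7 adjusted over the list alone), with Tef at -0.52 and Per3 at -0.63, or 0.11 and 0.19 with the score terms (camera adjusted p = 0.00243, adjusted p = 0.149 with an estimated correlation). Immediate early genes had 6 lower of 16 (6 adjusted over the list alone), with Egr3 at -0.83 and Jun at -0.53 (camera adjusted p = 0.00583, adjusted p = 0.29 with an estimated correlation). JAK-STAT genes had 11 lower and 4 higher of 25 (14 and 4 adjusted over the list alone), with Il4ra at -0.56 and the phosphatase gene Ptpn6 at -0.40 (camera adjusted p = 0.0103, adjusted p = 0.335 with an estimated correlation). Lists that camera did not call included T cell markers (0 higher and 4 lower of 19, mean -0.12), plasma cell markers (2 and 1 of 16, mean 0.38), monocyte markers (4 and 2 of 12, mean 0.27) and red pulp macrophage markers (4 and 1 of 17, mean 0.01). MHC class I genes had 3 higher and 1 lower of 19, regulatory T cell markers 1 and 0 of 7, stem and progenitor markers 1 and 1 of 12, and inflammatory cytokines and chemokines 0 and 3 of 27, with a positive mean of 0.22 and a camera direction of lower. Of these, fry called the monocyte (adjusted p = 0.0105) and stem and progenitor lists (0.042), and their scores also differed (exact permutation, adjusted p = 0.0253 for both). Adjusted over the list alone, these counts were unaltered except for plasma cell markers (0 higher and 1 lower) and inflammatory genes (0 and 2). The red pulp macrophage and regulatory T cell lists had positive means and negative medians of -0.03 and -0.01. Adipocyte markers had 1 higher of 8, skeletal muscle markers 1 of 5, and mesothelial and epithelial markers, mitochondrially encoded genes and the sex check genes 0 called in either direction. Among the lists camera called, the sign of the mean held under the 4 other scalings; it turned for the red pulp macrophage, MHC class I and regulatory T cell lists.

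Interferon-stimulated genes moved in both directions. Of 60 type I interferon-stimulated genes, 17 were higher and 12 lower in Dp16 (22 and 14 adjusted over the list alone), with a mean log2 fold change of 0.19 (camera adjusted p = 0.176, adjusted p = 0.646 with an estimated correlation, fry adjusted p = 0.0363). The members with the smallest p were Slfn8 (-0.67), Ifi209 (-0.49), the interferon regulatory factor gene Irf7 (0.76) and Samd9l (-0.63). The per-library score of the list was 5.49 ± 0.12 in WT and 5.69 ± 0.09 in Dp16 (SD, n = 6), a difference of 0.19 (exact permutation p = 0.013, adjusted p = 0.0253). Without Dp16 replicate 1 or 3 the adjusted p was 0.0518, and on RPKM 0.327. With the erythroid and neutrophil scores as terms the mean log2 fold change of the list turned to -0.08. Of 40 interferon gamma-stimulated genes 2 were higher and 6 lower (2 and 3 adjusted over the list alone). The mean was 0.04 while camera put the direction as lower (adjusted p = 0.705) and the sign of the mean turned with upper quartile scaling (-0.02) and RPKM (-0.09), with the score terms (-0.05), and without WT replicate 1 (-0.00) or 4 (-0.01). Named members were Ciita (-0.63), Gbp9 (-0.45), Gbp2b (1.09) and Igtp (0.36). The Gbp2b call was lost without the libraries rich in Gm42418 (1.02, adjusted p = 0.0642) and the Igtp call on RPKM (0.25, adjusted p = 0.0666).

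**Figure D2:**
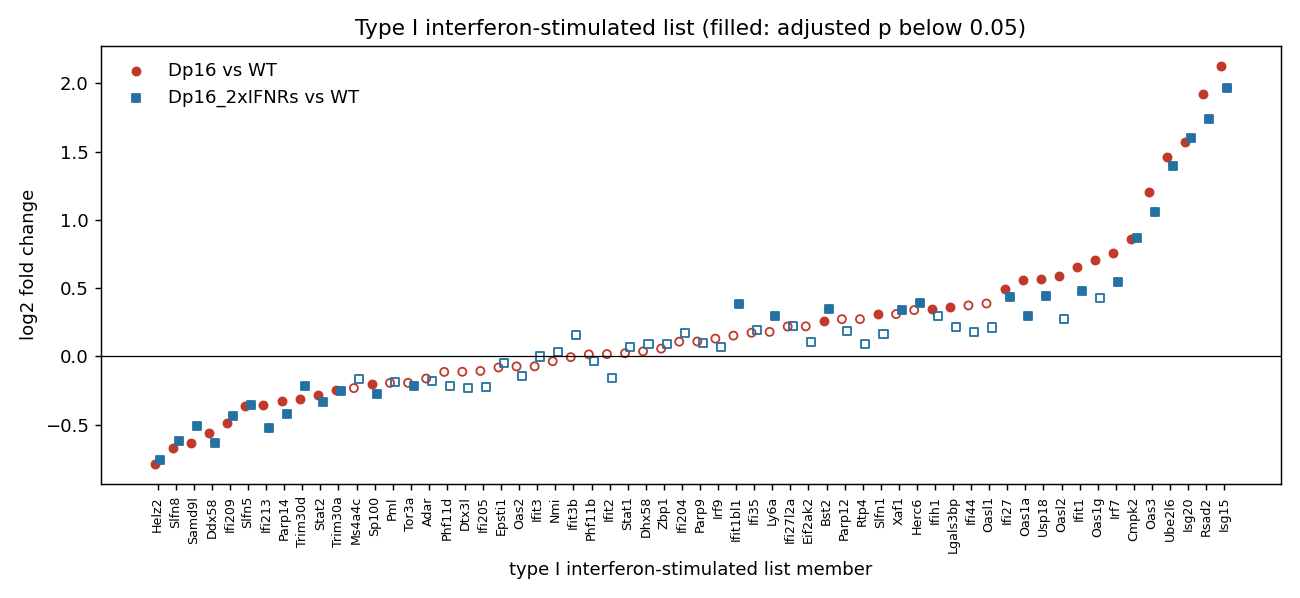
Log2 fold change against WT of members of the type I interferon-stimulated list (n = 6 per genotype), with red circles for Dp16 and blue squares for Dp16_2xIFNRs; filled symbols have an adjusted p below 0.05. Of 60 members 17 are filled above 0 and 12 below 0 in Dp16, and 16 and 13 in Dp16_2xIFNRs.

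The comparison of Dp16_2xIFNRs with WT asks which of these changes are present when the receptors are at the normal copy number. The interval genes, the granulocyte, red cell, platelet and basophil genes were again higher and the B cell genes lower, while the receptors stood near or below WT. Besides the interval, the neutrophil list alone kept its call with an estimated correlation, 1 of 19 lists called (adjusted p = 0.0272), against an adjusted p of 0.191 for erythroid, 0.168 for platelet and basophil and 0.141 for B cell genes. Of all genes 3217 were higher and 2643 lower (799 and 142 above 2-fold). The 109 interval genes without receptors had a median log2 fold change of 0.55, with 55 higher and 0 lower (59 and 0 adjusted over the list alone; camera adjusted p = 1e-20, and adjusted p = 5.1e-08 with an estimated correlation). Among the receptors, Ifngr2 was lower (-0.27 ± 0.08 SE, adjusted p = 0.0147). Ifnar1 (-0.17, adjusted p = 0.106), Il10rb (-0.07, adjusted p = 0.442) and Ifnar2 (0.09, adjusted p = 0.276) were not called. Ifnar1, whose adjusted p ran from 0.0188 to 0.276 over the alternatives, was called lower with upper quartile scaling (adjusted p = 0.0224), RPKM (0.0188) or a library index term (0.0439) and without WT replicate 6 (0.0451) or Dp16_2xIFNRs replicate 2 (0.036). RPKM also called Il10rb lower (0.0239) and turned Ifnar2 to -0.03, and the score terms turned it to -0.07. The score of the 4 receptors was 6.33 ± 0.06 against 6.44 ± 0.04 in WT (SD, n = 6), a difference of -0.11 (exact permutation p = 0.00649, adjusted p = 0.0142). Without the 4 libraries with over 4% of counts on Gm42418, 1734 genes were lower.

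The genes with the smallest p were largely the genes named for Dp16. Higher were Ly6a2 (1.94 ± 0.15 SE), Wfdc21 (2.46), Lin28a (2.17), a (4.65), Pglyrp1 (1.26), Ifitm6 (1.61), Rab44 (1.77) and Cd177 (2.28). Lower were Fcmr (-0.92 ± 0.09 SE), Dmpk (-0.78), Zfp318 (-1.02), Bmf (-0.94), Sbk1 (-0.97), Cr2 (-0.82), Tut4 (-0.73) and Chst3 (-1.06). Of the called genes 54.9% were higher, against 43.7% with upper quartile scaling and 36.8% with RPKM, where the median of all genes was -0.12. Neutrophil markers had 16 higher and 0 lower of 18 (16 and 0 adjusted over the list alone), a mean of 2.05, and Fcnb and S100a9 at 2.42 and 2.34 (camera adjusted p = 9.7e-34, adjusted p = 0.0272 with an estimated correlation). All 26 erythroid markers (26 adjusted over the list alone), all 12 haem synthesis genes (12) and all 30 cell cycle genes (30) rose, with means of 1.75, 1.44 and 1.16. Examples were Car1 (1.47), Hbb-bs (1.56), Urod (1.64), Cpox (1.73), Mcm3 (0.85) and Mcm5 (0.87). Their adjusted p was 2.2e-17, 1.1e-09 and 1.6e-25 by camera, and an adjusted p of 0.191, 0.168 and 0.168 with an estimated correlation.

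Megakaryocyte markers had 15 higher of 16 (15 adjusted over the list alone), with Clec1b at 0.75 and Gp9 at 1.29, and mast cell and basophil markers 6 of 9 (7 adjusted over the list alone), with Prss34 at 3.49 and Mcpt8 at 3.70. Their camera adjusted p was 3.1e-12 and 3.8e-05, and an adjusted p of 0.168 for both with an estimated correlation. B cell markers had 15 lower of 16 (15 adjusted over the list alone), with a mean of -0.59 (camera adjusted p = 4.35e-13, adjusted p = 0.141 with an estimated correlation). Camera also called plasma cell markers higher, with 5 higher and 1 lower of 16 (5 and 1 adjusted over the list alone), Jchain at 0.73 and Irf4 at -0.44 (adjusted p = 0.0154, adjusted p = 0.553 with an estimated correlation). Monocyte markers had 5 higher and 0 lower of 12 (5 and 2 adjusted over the list alone), with Itgam at 0.85 and Ly6c2 at 0.58 (camera adjusted p = 0.023, adjusted p = 0.374 with an estimated correlation). T cell markers had 5 lower of 19 (5 adjusted over the list alone), with Cd8a at -0.59 (camera adjusted p = 0.0311, adjusted p = 0.616 with an estimated correlation, fry adjusted p = 0.0859).

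Other lists called in Dp16_2xIFNRs vs WT were antioxidant genes (Txn1 0.60, Gsr 0.46), unfolded protein response genes (Atf4 0.49, Manf 0.60) and germinal centre markers (Rgs13 1.29, Neil1 0.43) as higher. Their camera adjusted p was 4.7e-05, 0.0189 and 0.0401. They had 9, 4 and 4 higher and 1, 0 and 1 lower, or 11, 6 and 7 higher and 1, 0 and 1 lower adjusted over the list alone, and an adjusted p of 0.141, 0.553 and 0.553 with an estimated correlation. The Rgs13 call was lost without the libraries rich in Gm42418 (1.01, adjusted p = 0.067) and the Neil1 call with limma-trend on RPKM (0.31, adjusted p = 0.0595). Called as lower were MHC class II (Ciita -0.62, H2-Ob -0.59), endothelial (Kdr -0.78, Pecam1 -0.37), stromal (Myh11 -1.13, Cxcl13 -0.68), NK and cytotoxic (Eomes -0.54, Klra8 -0.67), circadian (Clock -0.53, Tef -0.48) and JAK-STAT genes (Il4ra -0.56, Il6ra -0.57). Their camera adjusted p was 0.00245, 0.000136, 0.000136, 0.0287, 0.00311 and 0.00354. They had 4, 7, 7, 5, 5 and 11 lower and 0, 0, 0, 0, 0 and 3 higher, or 5, 7, 7, 5, 5 and 13 lower and 0, 0, 1, 0, 0 and 4 higher adjusted over the list alone, and an adjusted p of 0.43, 0.23, 0.301, 0.43, 0.181 and 0.301 with an estimated correlation. With the score terms Klra8 turned to 0.25 and Tef to 0.12. Type I interferon-stimulated genes had 16 higher and 13 lower of 60 (17 and 14 adjusted over the list alone), with Slfn8 at -0.62, Ddx58 at -0.63, Ifi209 at -0.44 and Isg15 at 1.96 (mean 0.15, and -0.12 with the score terms; camera adjusted p = 0.542). Interferon gamma-stimulated genes had 2 higher and 4 lower of 40 (0 and 3 adjusted over the list alone), with Ciita at -0.62, Gbp9 at -0.42, Nlrc5 at -0.40 and Gbp2b at 0.94. The Gbp2b call was lost without WT replicate 1 (0.79, adjusted p = 0.0555), Dp16_2xIFNRs replicate 2 (0.75, adjusted p = 0.074) or the libraries rich in Gm42418 (0.88, adjusted p = 0.0842). Its value was -0.07 with the score terms. The gamma mean of 0.00 had a camera direction of lower (adjusted p = 0.542), and its sign turned with RLE, upper quartile and RPKM scaling and with the score terms (-0.08). The type I score differed from WT by 0.14 (exact permutation p = 0.026, adjusted p = 0.0455). That adjusted p rose above 0.05 without WT replicate 1 (0.0758), 3 (0.0589), 4 (0.0797) or 6 (0.0626), and without Dp16_2xIFNRs replicate 1 (0.0758), 2 (0.0833), 3 (0.0606), 5 (0.093) or 6 (0.0866). It also did with RLE (0.0613), upper quartile (0.0845) and RPKM scaling (0.61), and without the libraries rich in Gm42418 (0.159). Lists that camera did not call in this contrast included dendritic cell markers (0 higher and 3 lower, the same adjusted over the list alone), immediate early genes (0 and 4, the same; adjusted p = 0.0502), inflammatory genes (4 and 3, or 0 and 2 adjusted over the list alone) and red pulp macrophage markers (5 and 1, the same). The others were MHC class I (3 and 1, or 2 and 1 adjusted over the list alone), stem and progenitor (0 and 3, or 0 and 0), regulatory T cell (1 and 0, the same), adipocyte (1 and 2, the same), skeletal muscle (1 and 0, the same), mesothelial and epithelial (0 and 2, or 0 and 0), mitochondrially encoded (0 and 1, or 0 and 0) and sex check genes (0 and 0, the same). Of these lists fry called the dendritic cell (adjusted p = 0.00949), immediate early (0.0248) and sex check lists (0.0381). By exact permutation of the scores, immediate early genes (adjusted p = 0.0455), inflammatory genes (0.0446) and stem and progenitor markers (0.0455) differed from WT. Of the lists camera called, MHC class II (adjusted p = 0.0541), plasma cell (0.0689), unfolded protein response (0.0823), germinal centre (0.0848) and T cell lists (0.129) did not pass.

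The comparison of Dp16_2xIFNRs with Dp16 asks what the extra receptor copies add. The 4 receptor genes were lower, and no other gene was called. The changes were -0.59 ± 0.06 SE for Ifnar2 (adjusted p = 3.7e-05), -0.54 ± 0.07 for Il10rb (adjusted p = 0.0005), -0.57 ± 0.08 for Ifngr2 (adjusted p = 0.00339) and -0.46 ± 0.08 for Ifnar1 (adjusted p = 0.0278). Group means in Dp16_2xIFNRs were 93.7 ± 5.17, 75.1 ± 5.71, 77.3 ± 8.59 and 77.7 ± 7.54 CPM (SD, n = 6). By edgeR 0 genes were higher and 0 outside the interval were lower, with 438 genes at an unadjusted p below 0.05 where 932 are expected by chance. A count below that expectation means p-values that are not evenly spread, so it cannot show that other genes were unaltered. DESeq2 and limma voom also gave 0 higher and 4 lower, and limma-trend on RPKM 0 and 3. The Ifnar1 call was lost without WT replicate 5 (adjusted p = 0.0511), Dp16 replicate 1 (0.0758), 2 (0.126), 4 (0.0916), 5 (0.117) or 6 (0.0622), or Dp16_2xIFNRs replicate 3 (0.14), 4 (0.0981), 5 (0.132) or 6 (0.12). It was also lost with RPKM (0.258), without the sex term (0.0744), with age as a term (0.0609), on 12 libraries (0.156) and without the 4 libraries rich in Gm42418 (0.24). Its log2 fold change stayed at -0.51 to -0.43 over left-out libraries and at -0.54 to -0.44 under the other alternatives. Its adjusted p ran from 0.000194 to 0.258 over all alternatives, with those that kept the call. The lncRNA A930006K02Rik, which lies among the receptors and was chosen after its values were seen, had a change of -0.84 with an adjusted p of 1. It was the interval gene called lower adjusted over the list alone. Its change was 0.97 in Dp16 vs WT (adjusted p = 0.00088) and 0.13 in Dp16_2xIFNRs vs WT (adjusted p = 0.686).

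The 109 other interval genes had a median of 0.00 between these genotypes, with 0 called by edgeR and 1 lower adjusted over the list alone. Of 60 type I and 40 gamma-stimulated genes 0 were called, also adjusted over the list alone, with means of -0.05 and -0.04 (camera adjusted p = 0.0724 and 0.816). The named members were Oasl2 (-0.32), Oas1a (-0.26), Ifit1bl1 (0.23) and Ifit2 (-0.17), and Cxcl10 (0.33), Gm4951 (-0.36), Gbp10 (-0.56) and Nos2 (0.28), each with an adjusted p of 1. Score differences were -0.05 (95% interval -0.14 to 0.05) for the type I list and -0.01 (-0.15 to 0.12) for the gamma list (n = 6 each, exact permutation). Camera put the type I list below its threshold, as lower, without Dp16 replicate 2 (adjusted p = 0.00992), Dp16 replicate 5 (0.0291) or Dp16_2xIFNRs replicate 5 (0.0136), with limma voom (0.00644) and without the libraries rich in Gm42418 (0.000674); over all alternatives this p ran from 0.000674 to 0.952. The list had an adjusted p of 0.915 with an estimated correlation and 0.952 by fry. Its score difference was called under no alternative (exact permutation, adjusted p from 0.486 to 0.958). It was -0.08 to -0.03 over left-out libraries and -0.09 without the libraries rich in Gm42418. A score could hardly be called in this contrast: the receptor score, at the smallest possible exact permutation p of 0.00216, had an adjusted p of 0.0758. Camera called dendritic cell markers (mean 0.13, Cd209a 0.51, Ccr9 0.26), inflammatory cytokines (mean 0.21, Cxcl10 0.33, Ccl4 0.84) and plasma cell markers (mean 0.22, Ighg1 0.85, Jchain 0.24) as higher, with 0 members called, also adjusted over the list alone. Their adjusted p was 0.0121, 0.0319 and 0.0319, and an adjusted p of 0.492, 0.915 and 0.915 with an estimated correlation. Without Dp16_2xIFNRs replicate 2 camera called 0 lists and without replicate 4 it called 1, and the Ighg1 value was 0.06 without replicate 6. The neutrophil score differed by -0.13 (95% interval -0.73 to 0.45), the erythroid score by -0.00 (-0.44 to 0.43), the cell cycle score by -0.04 (-0.34 to 0.27) and the B cell score by 0.05 (-0.14 to 0.23), by exact permutation.

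**Figure D3:**
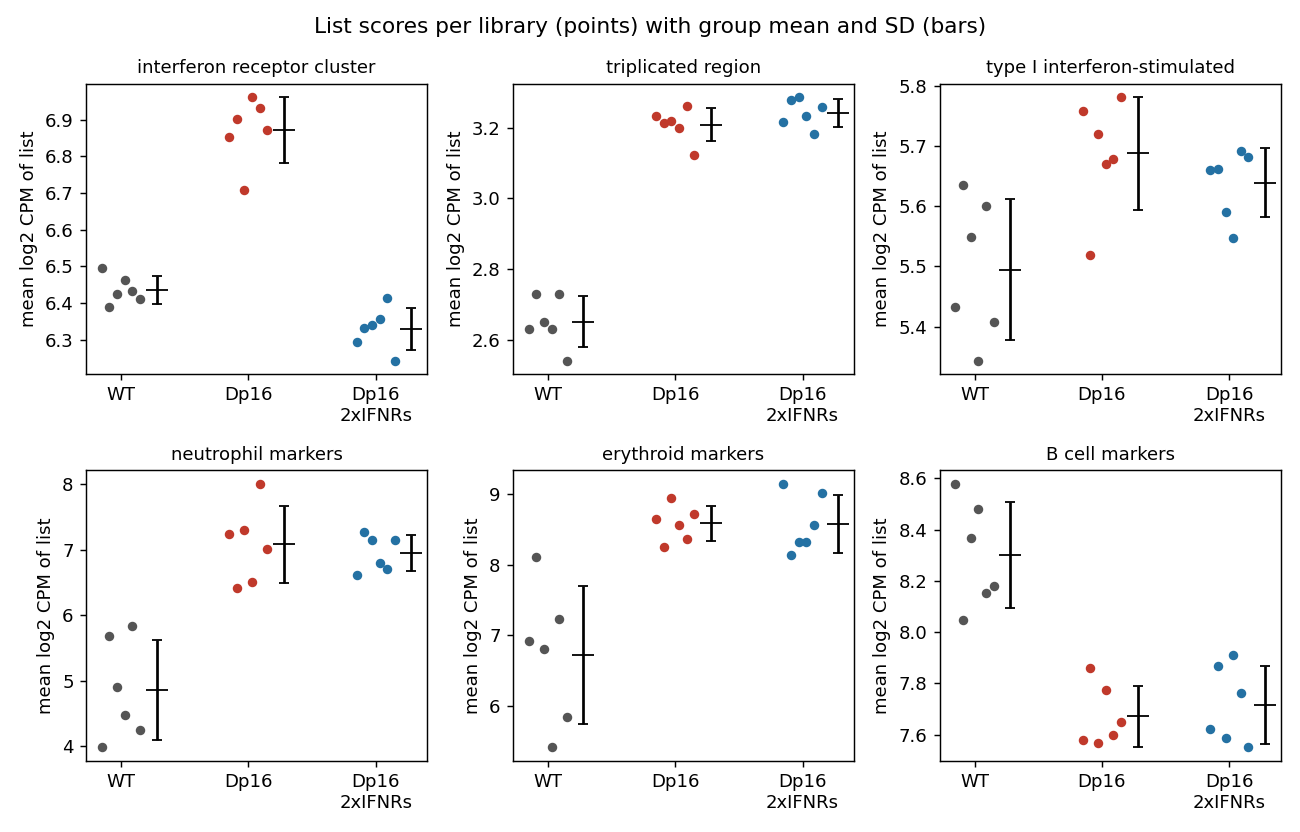
List scores (mean log2 CPM of members, vertical axes) per library for the 3 genotypes; points are libraries and bars give the group mean and SD (n = 6). The receptor score is 6.44 in WT, 6.87 in Dp16 and 6.33 in Dp16_2xIFNRs.

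Changes against WT were shared by the 2 genotypes with the extra interval. Outside it, 2720 genes were higher and 1998 lower in both contrasts, where 516 and 351 would be shared by chance, and 0 were called in opposite directions. Both contrasts use the same WT libraries, which alone gave a correlation across genes of 0.49 in simulated unchanged groups with 0 shared calls, against 0.82 observed (genes are not independent replicates). The covariance was 0.31 against 0.0755 in the simulation. Genes were drawn independently there, so variation that runs across many genes of the shared WT libraries was left out of this baseline. With WT divided into 3 and 3 libraries, 1 part per contrast, 1467 higher and 923 lower genes were shared in 1 arrangement and 1607 and 1051 in the other, with correlations of 0.55 and 0.57.

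No gene was called for a sex by genotype interaction by edgeR in the 3 contrasts. At an unadjusted p below 0.05 there were 439, 745 and 425 genes, where 932 are expected by chance. Counts below that expectation mean p-values that are not evenly spread, so they cannot show that interactions were absent. limma voom gave 0, 0 and 0, and DESeq2 gave 1, 0 and 5. The DESeq2 genes were Capn11 for Dp16 vs WT, and Klhl32, Igkv10-95, Gm26760, 4732465J04Rik and Gm36423 for Dp16_2xIFNRs vs Dp16, named after they were seen. Each sex had 3 animals per genotype.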

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

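In 11 of 318 sets of 6 libraries 1 library stood apart from the other 5 of its genotype, by a gap to the nearest of more than 0.625 of the whole range, where about 15.9 sets would by chance; none of these was tested further. Of them, 4 were in Dp16 replicate 6, 2 in Dp16 replicate 2 and 1 each in 5 other libraries. In Dp16 replicate 6, log2 CPM was 5.25 for Dmpk (others 4.93 to 5.05), 3.88 for Bmf (4.23 to 4.41), 4.06 for Gcsam (4.82 to 5.10) and 1.78 for Per3 (2.19 to 2.38). In Dp16 replicate 2 it was 6.14 for Igtp (6.38 to 6.47) and 6.49 for the T cell gene Cd8a (5.89 to 6.05). Ifngr2 was at 6.56 in Dp16 replicate 3 (6.85 to 6.96), Samd9l at 7.56 in WT replicate 1 (6.94 to 7.15), Rgs13 at 1.86 in Dp16_2xIFNRs replicate 1 (2.94 to 3.28) and Ccl4 at 0.50 in Dp16_2xIFNRs replicate 3 (1.47 to 2.05). Dp16_2xIFNRs replicate 2 had 53.02 M total counts (40.6 to 44.3).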

How the results depend on the processing

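The alternatives with Gm42418 or with the erythroid and neutrophil scores were chosen after seeing the data; the cause of each change below was not tested unless stated. For named genes, 1256 of 1260 values with 1 library left out kept their direction and side of the threshold in Dp16 vs WT, 1112 of 1116 in Dp16_2xIFNRs vs WT and 296 of 306 in Dp16_2xIFNRs vs Dp16, and 1318 of 1329, 1169 of 1177 and 317 of 322 did under the other alternatives, the score terms aside. These genes were named largely for a small p in the same libraries, so the counts say little about other called genes. In Dp16_2xIFNRs vs Dp16, where 4 of the 17 named genes were called, the 10 values that changed side with 1 library left out all belonged to Ifnar1. Genes higher ran from 2238 to 3592 in Dp16 vs WT and from 2328 to 3762 in Dp16_2xIFNRs vs WT over the other alternatives, the score terms aside. The interval median stayed between 0.37 and 0.58, and between 0.40 and 0.57. In simulated data edgeR recovered 32% of 1.5-fold changes in Dp16 vs WT and 44% in Dp16_2xIFNRs vs Dp16. Far fewer genes were changed there than were called against WT, so these shares may not hold for the contrasts against WT.

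With limma-trend on RPKM, which moved the median of all genes, 3946 genes were lower in Dp16 vs WT and 3994 in Dp16_2xIFNRs vs WT, 3201 of them shared, and Ifnar2 was at -0.025 in Dp16_2xIFNRs vs WT. Without the 4 libraries rich in Gm42418, 1734 genes were lower in Dp16_2xIFNRs vs WT and 1161 shared, with fewer libraries. DESeq2 called 1 sex interaction in Dp16 vs WT and 5 in Dp16_2xIFNRs vs Dp16.

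Lists called in Dp16_2xIFNRs vs Dp16 were 3, against 7 with DESeq2, 9 with limma voom, 1 with limma-trend on RPKM, 1 with no filter, 8 at an adjusted p below 0.1, 5 with age, 6 with library index, 7 on 12 libraries, 5 with a replicate block (0 and 4 genes called), 1 with a description-code block, 1 with the Gm42418 term, 6 without the libraries rich in Gm42418, 0 with an estimated correlation and 0 with fry. Leaving out 1 library gave 0 to 11: 5 without WT replicate 1 or 3, 5, 11 and 8 without Dp16 replicate 1, 2 and 5, and 6, 0, 1, 8 and 5 without Dp16_2xIFNRs replicate 1, 2, 4, 5 and 6. Against WT an estimated correlation called 1 list in each contrast.

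The type I mean in Dp16_2xIFNRs vs Dp16 (-0.046) passed the threshold with limma voom (-0.076), without the libraries rich in Gm42418 (-0.092) and at an adjusted p below 0.1 (-0.046, adjusted p = 0.0724). Leaving out 1 library gave -0.068 to -0.0095, past the threshold without Dp16 replicate 2 (-0.068) or 5 (-0.057) or Dp16_2xIFNRs replicate 5 (-0.068). It did not with an estimated correlation (adjusted p = 0.915) or fry (0.952), and its score difference passed under no alternative (exact permutation, adjusted p from 0.486 to 0.958, and -0.083 to -0.030 over left-out libraries). That test could hardly pass in this contrast, since the receptor score, at the smallest p it can give, had an adjusted p of 0.0758. In Dp16 vs WT the type I mean (0.19) passed with fry (adjusted p = 0.0363). The type I score in Dp16 vs WT lost its call on RPKM (0.076) and without Dp16 replicate 1 (0.18) or 3 (0.19), with 0.16 to 0.23 over left-out libraries. In Dp16_2xIFNRs vs WT it lost its call with RLE (0.14), upper quartile (0.082), RPKM (0.029) and without the libraries rich in Gm42418 (0.10). It also did without WT replicate 1 (0.13), 3 (0.15), 4 (0.11) or 6 (0.13) or Dp16_2xIFNRs replicate 1 (0.14), 2 (0.14), 3 (0.15), 5 (0.13) or 6 (0.14), with 0.11 to 0.17 over left-out libraries.

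Gamma values near 0 changed sign. The mean in Dp16 vs WT was -0.022 with upper quartile and -0.089 with RPKM, and -0.0087 to 0.095 over left-out libraries (-0.00088 without WT replicate 1, -0.0087 without 4). In Dp16_2xIFNRs vs WT it was -0.0047 with RLE, -0.057 with upper quartile, -0.0046 with DESeq2, -0.11 with RPKM, -0.024 with no filter, -0.016 with the CPM filter, -0.016 without immunoglobulin, haemoglobin and acinar genes, -0.0030 with the Gm42418 term and -0.042 without the libraries rich in it. Over left-out libraries it was -0.044 to 0.057 (-0.036 and -0.044 without WT replicate 1 and 4; -0.018, -0.013 and -0.016 without Dp16_2xIFNRs replicate 2, 3 and 5). In Dp16_2xIFNRs vs Dp16 it was 0.0073 with limma voom and -0.069 to 0.0020 over left-out libraries (0.0020 without Dp16_2xIFNRs replicate 6). The gamma score in Dp16 vs WT was -0.089 on RPKM and -0.038 with upper quartile, and -0.025 to 0.068 over left-out libraries (-0.014 and -0.025 without WT replicate 1 and 4). In Dp16_2xIFNRs vs WT it was -0.11 on RPKM, -0.052 with upper quartile and -0.057 without the libraries rich in Gm42418, and -0.039 to 0.053 over left-out libraries. It was -0.028 and -0.039 without WT replicate 1 and 4, and -0.0076, -0.0014 and -0.0079 without Dp16_2xIFNRs replicate 2, 3 and 5. In Dp16_2xIFNRs vs Dp16 it was -0.047 to 0.025 over left-out libraries (0.0030 without Dp16 replicate 5, 0.025 without Dp16_2xIFNRs replicate 6). The interval median in Dp16_2xIFNRs vs Dp16 was -0.0032 with the CPM filter and -0.0030 to 0.021 over left-out libraries (-0.00075 without WT replicate 3, -0.0030 without Dp16 replicate 2). Adamts1 in Dp16 vs WT was at -0.48 to 0.031 (0.031 without WT replicate 6).

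With the erythroid and neutrophil scores as terms, 0 genes were higher and 0 lower in Dp16 vs WT, 0 and 1 in Dp16_2xIFNRs vs WT, and 0 and 0 were shared, while the median standard error grew from 0.154 to 0.452 and 0.430. The median of all 113 interval genes was 0.51 and 0.57, from 0.50 and 0.53. Then 10 lists were called in each contrast, the type I mean was -0.083 and -0.12 and the gamma mean -0.054 and -0.080. In Dp16 vs WT, Itgb2l was at -0.20, Brwd1 0.71, Tcf4 0.20, Ly6d 0.050, Gp9 -0.072, Tef 0.11, Per3 0.19 and Calr -0.089. In Dp16_2xIFNRs vs WT, Ifnar2 was at -0.073, Gbp2b -0.065, Klra8 0.25 and Tef 0.12. Of 70 and 62 named genes, 60 and 56 kept their direction and lost their call.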

Other observations

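The tests in this part were chosen only after the results were seen, except for the random splits of the libraries. Among 60 type I interferon-stimulated genes, the 17 members higher in Dp16 included Isg15 (log2 fold change 2.13), a ubiquitin-like modifier, the antiviral enzyme gene Rsad2 (1.92), Isg20 (1.57), Ube2l6 (1.46) and Oas3 (1.20). The 12 lower members included Helz2 (-0.79), the RNA sensor gene Ddx58 (-0.56), Parp14 (-0.33) and the signalling gene Stat2 (-0.28). These were named after their values were seen.

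Chance assignment of libraries to genotypes can be excluded for the count of 5553 genes in Dp16 vs WT, which 1 of 100 splits reached, the real one (highest other 1782, with Dp16 replicate 4 and WT replicate 2 exchanged). It can be excluded for the 5860 genes in Dp16_2xIFNRs vs WT, which 1 of 100 splits reached (highest other 4443, with Dp16_2xIFNRs replicate 2 and WT replicate 2 exchanged). For the 4 genes in Dp16_2xIFNRs vs Dp16, 2 of 100 splits reached as many, the real one included, a share below 0.05. The highest other called 21, which points to a structure of the samples, so the count of 4 alone does not exclude chance. That split largely follows the library index of the labels, whose meaning is not stated, and with the index as a term the real comparison called 0 genes higher and 4 lower. WT replicate 2 had the WT erythroid score nearest to the other genotypes, 8.11 against a WT mean of 6.72.

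The first pattern is the large number of genes called between the genotypes with the extra interval and WT. The share of counts on Gm42418 is argued against, since 5556 genes were called in Dp16 vs WT with it as a term. An equal dilution of all other cells by red cells and granulocytes is argued against, since the B cell minus T cell score was 1.253 in Dp16 and 1.758 in WT, a difference of -0.51 (exact permutation p = 0.00216, the smallest it can give, 6 of 6 Dp16 libraries against 6 WT). A cell mix that differs by genotype stays open as a candidate explanation. With the erythroid and neutrophil scores as terms, 0 genes were called by edgeR, and 8 of 70 named genes turned in sign. The median standard error grew from 0.154 to 0.452, since these scores separate WT from both other genotypes, so this fit cannot decide. The median log2 fold change of all 113 interval genes was 0.50 before and 0.51 after. Changes within cells caused by the extra interval stay open, and were not tested.

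The second pattern is that type I interferon-stimulated members moved both ways. Within genotypes, the 17 higher members may follow red cell content, granulocyte content or both, with r = 0.86 to the erythroid score (rho = 0.87, permutation p = 6e-05, adjusted over 4 relations 0.00024; 0.71 without the 2 farthest libraries; 0.94, 0.89 and 0.81 in WT, Dp16 and Dp16_2xIFNRs), as high as in 17 of 1000 random lists. Their r to the neutrophil score was 0.60 (rho = 0.62, permutation p = 0.032, adjusted 0.0426; 0.69 without the 2 farthest; 0.78, 0.48 and 0.04 by genotype). The 12 lower members may follow B cell content, with r = 0.63 to the B cell score (rho = 0.64, permutation p = 0.0089, adjusted 0.0178; 0.63 without the 2 farthest; 0.91, 0.60 and 0.38 by genotype), as high as in 30 of 1000 random lists. The random lists were drawn from expressed genes outside the interval, not from genes called in the same direction. They cannot show that these members follow the scores more closely than other called genes. Receptor dosage as a source of the higher members' rise stays open: their mean, of members picked in Dp16 vs WT, differed by -0.14 between Dp16_2xIFNRs and Dp16 (95% interval -0.38 to 0.12, exact permutation p = 0.24), where a loss of 0.5 of the rise needs -0.44, and without the libraries rich in Gm42418 by -0.19 (-0.43 to 0.07), where it needs -0.42. With 1 library left out the difference ran from -0.22 without Dp16 replicate 2 to -0.09 without Dp16_2xIFNRs replicate 4. Without Dp16 replicate 2 the 95% interval was -0.42 to -0.02, where a loss of 0.5 of the rise needs -0.48. Members picked as higher in these same Dp16 libraries can give a difference below 0 without any effect of dosage. Neither its sign nor an interval below 0 is therefore evidence for dosage.

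The third pattern is the gene a, with 3 to 30 counts in WT, 191 to 473 in Dp16 and 232 to 569 in Dp16_2xIFNRs. Erythroid content as the whole source is argued against, since with the erythroid score as a term the log2 fold change in Dp16 vs WT was 3.55 (95% interval 2.40 to 4.70), from 4.50 without it. The standard error grew from 0.364 to 0.553 with this term, and the interval, which includes that growth, stayed above 0. Within genotypes a had r = 0.36 to the erythroid score (permutation p = 0.344, r = -0.06 without the 2 farthest libraries). By genotype r was 0.25 in WT, 0.72 in Dp16 and 0.78 in Dp16_2xIFNRs, so a part of its level may follow red cell content. A strain variant shared by the neighbourhood cannot be told apart from 1 acting on a alone: of 153 tested genes within 5 Mb, 48 were called, 31.4% against 29.6% elsewhere (Fisher's exact p = 0.344), and a variant at a single gene leaves no trace in its neighbours. Other sources stay open and were not tested, among them a variant of the strain background at a and a change caused by the extra interval.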
